A study of Escherichia coli with 8 samples.

How the data were processed

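RNA of Escherichia coli BW25113, a laboratory K-12 strain, was compared on 2-colour DNA microarrays. Per the labels' protocols, cells were grown aerobically to mid-log phase at 37 °C in MOPS medium with 0.5% glucose, shaken at about 250 RPM, and either left untreated or given 100 uM KCN for 5 minutes. RNA was taken with hot phenol and chloroform and a Qiagen column and labelled by direct incorporation of dCTP, per the labels. Treated and untreated RNA shared each array, so each array gave its own ratio. There were 4 biological samples, each on 2 technical arrays, making 8 arrays. KCN RNA carried Cy5 in samples 1, 2 and 4 and Cy3 in sample 3, per the labels.

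The deposited scanner files hold spot intensity, 1 dye per file, quantified with ImaGene 6.0.1 per the file headers. Background was not subtracted in them, as dim spots lay close to their local background. Per the file headers, empty spots were flagged automatically, and other spots carried a flag set by hand. The authors' value table holds log10 ratios. Its base and direction are not given in the sources used here and were worked out from the values. Against log2 Cy5 over Cy3 of the scanner files, the slope was between 0.298 and 0.302 on all 8 arrays, as log10 of Cy5 over Cy3 gives, with r between 0.964 and 0.997. Column medians lay between -0.004 and 0.005, and flagged spots held 0 values. The series design text names ImaGene and the lcDNA package; the settings used with lcDNA are not given in the sources used here.

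Each array held 13440 spots in 8 rows and 4 columns of blocks, of which the authors' value table lists 9480. The listed spots formed 4740 pairs of an odd number and the next even number, printed 4 block rows apart. Intensity correlated at r = 0.937 across spots within such pairs and at -0.036 between an even spot and the next odd one, so each pair was treated as 1 probe printed on 2 spots. The gene column of the scanner files is empty and the files do not pair spots with genes. Results are therefore given per spot pair, and spot numbers were never turned into gene names. The 41 gene lists fixed for this comparison, and 15 genes that were to be reported in any case, are not analysed here for the same reason.

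Ratios were computed with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. Signal means were corrected with background medians by normexp with an offset of 50, and log2 ratios were normalised within each array by loess. Flagged and unlisted spots had weight 0 in loess, and flagged spots were then left out. Spots of a pair and then the technical arrays of a sample were averaged, and the sign was turned so that positive values mean higher with KCN. A pair needed a value in at least 3 of the 4 samples. The mean log2 ratio was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; the prior degrees of freedom were 5.24. A separate model gave each pair's dye effect beside its KCN effect, for pairs in which both could be estimated. A spot was above background when its mean exceeded the local background by 2 background SDs. Saturated spots, with a signal median of 65535, were kept. Clipping of part of a spot's pixels was not checked.

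The tests, the alternatives and the rule for naming results were fixed before the data were examined. The rule took the 15 largest rises and the 15 largest falls among pairs that passed the test, were measured in all 4 samples and changed the same way in each. Since spots carry no gene names, only the first 2 of each direction are named here, and the remainder are given as ranges. In all, 29 alternatives were run, 6 of them added after the data were seen.

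The steps were tested on simulated data with the brightness of the real arrays, in which 200 of the listed pairs changed by known amounts. Of the changed pairs among the 4714 tested, 71.6% of those set to a log2 change of 0.5 were recovered, and 100% of those set to 1 or 2, none in the wrong direction. Of 190 calls, 12 were false, and data simulated with no change gave 0 calls. These rates hold for the noise that was simulated. They do not show whether calls in the real arrays arose from dye effects of single probes or from the dye-swapped sample. Nothing in the labels says whether the 4 biological samples came from separate cultures beyond their name, so p-values measure the spread between these samples. The number of biological samples, rather than that of arrays, limits the precision.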

Results

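Transcript ratios were measured in aerobic E. coli BW25113 after 5 minutes of 100 uM KCN, against untreated cells. Cyanide binds the haem of terminal respiratory oxidases. There was 1 comparison, KCN over untreated, made in 4 biological samples on 2 technical arrays each. The median Cy3 intensity of an array lay between 569.3 and 1709, and that of Cy5 between 628.2 and 3003, over local backgrounds with medians between 4 and 22 in Cy3 and between 69 and 130 in Cy5. Between 91.1% and 99.3% of listed spot pairs were above background in Cy3, and between 85.7% and 99.2% in Cy5. Of the listed pairs, 3627 were above background on all 8 arrays in both conditions.

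The comparison asked which transcripts changed within minutes of cyanide. Of 4714 spot pairs tested, 351 were higher and 514 lower with KCN at a Benjamini-Hochberg adjusted p under 0.05 with limma. Together these 865 pairs made up 18.3% of those tested, and 40.6% of them were higher. Of the pairs called higher, 342 were higher in all 4 samples, and 510 of those called lower were lower in all 4. Most changes were small. The median called pair rose by a log2 ratio of 0.44, or 1.36-fold, or had a log2 ratio of -0.48, or 1.39-fold lower.

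Changes of at least 2-fold were found for 37 pairs that rose and 42 that fell. Under 1.5-fold stood 243 of the higher and 335 of the lower pairs. The smallest called changes were 0.24 and -0.24 on the log2 scale, and the median standard error over all pairs was 0.085. The spread between biological samples, as a root mean square SD of log2, was 0.21. That between technical arrays of a sample was 0.18, and that between the 2 spots of a pair 0.24. These values are not on a common scale. The 0.21 is for means of 2 arrays, the 0.18 for arrays with both spots averaged and the 0.24 for single spots. Over pairs with 4 values, 41.3% changed the same way in all 4 samples, where 12.5% would if signs were independent between samples. Samples 1, 2 and 4 share a dye orientation, so with a dye bias of single probes that 12.5% would not apply.

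The largest rise was that of spots 7829 and 7830 (spots_7829_7830), with a mean log2 ratio of 2.63 ± 0.42 (SD, n = 4), or 6.20-fold (limma, Benjamini-Hochberg adjusted p = 3.03e-05). Its 4 samples gave 2.67, 2.66, 3.11 and 2.09. Spots 4529 and 4530 (spots_4529_4530) rose by 2.51 ± 0.22 (SD, n = 4), or 5.70-fold (limma, adjusted p = 6.87e-06). Both were above background on all 8 arrays in both conditions. The order of these 2 rises turned in some alternatives. Spots 7829 and 7830 stood at 2.47 against 2.51 without sample 3, and at 2.36 against 2.61 with technical array 2 alone. On quantification day 2 alone they stood at 2.60 against 2.66. In the remaining alternatives the order held. The largest fall was that of spots 1015 and 1016 (spots_1015_1016), at -2.74 ± 0.39 (SD, n = 4), which is 6.70-fold lower (limma, adjusted p = 1.85e-05). With KCN this pair was above background on 5 of the 8 arrays, against 8 untreated. Spots 4455 and 4456 (spots_4455_4456) stood at -2.17 ± 0.88 (SD, n = 4), 4.50-fold lower (limma, adjusted p = 0.0013), and were above background with KCN on 6 of 8 arrays. The samples of this pair ranged from -1.20 to -3.20, the widest of the 4 pairs. With the deposited log ratios spots 7829 and 7830 stood at 3.38 and spots 1015 and 1016 at -3.67, or 10.4-fold higher and 12.7-fold lower. Spots 4455 and 4456 stood at -1.48 on quantification day 1 alone and -2.86 on day 2 alone. No spot of the 4 pairs had a saturated signal median on any array. Over the 15 largest rises the log2 ratio ran from 2.63 to 1.34, and over the 15 largest falls from -2.74 to -1.54.

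**Figure D1:**
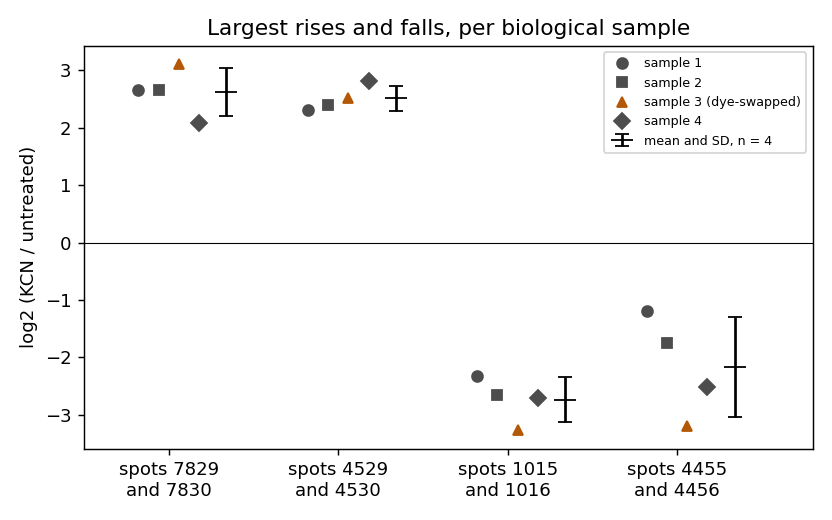
Log2 ratio of KCN over untreated for the 2 largest rises and 2 largest falls, 1 symbol per biological sample, with the dye-swapped sample in orange and bars for mean and SD (n = 4). All 4 samples lie on the same side of 0 for each pair, and spots 4455 and 4456 spread most, from -1.20 to -3.20.

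Over all called pairs, rises and falls had similar brightness, with median mean log2 intensities of 10.23 and 10.26. Pairs were divided by brightness into 5 bins of equal size, and from the dimmest bin to the brightest 60, 54, 69, 86 and 82 pairs were higher and 64, 87, 115, 125 and 123 lower. Changes of at least 2-fold were placed differently: of such rises, 22 of 37 were in the brightest bin, against 5 of 42 falls of that size (Fisher's exact test, two-sided, p = 1.14e-05, a comparison chosen after the counts were seen). Spot pairs are not independent replicates. Brightness was the mean of the KCN and untreated signals, so a rise itself raised it and a fall lowered it. Part of this difference was therefore built in, by an amount that was not measured.

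**Figure D2:**
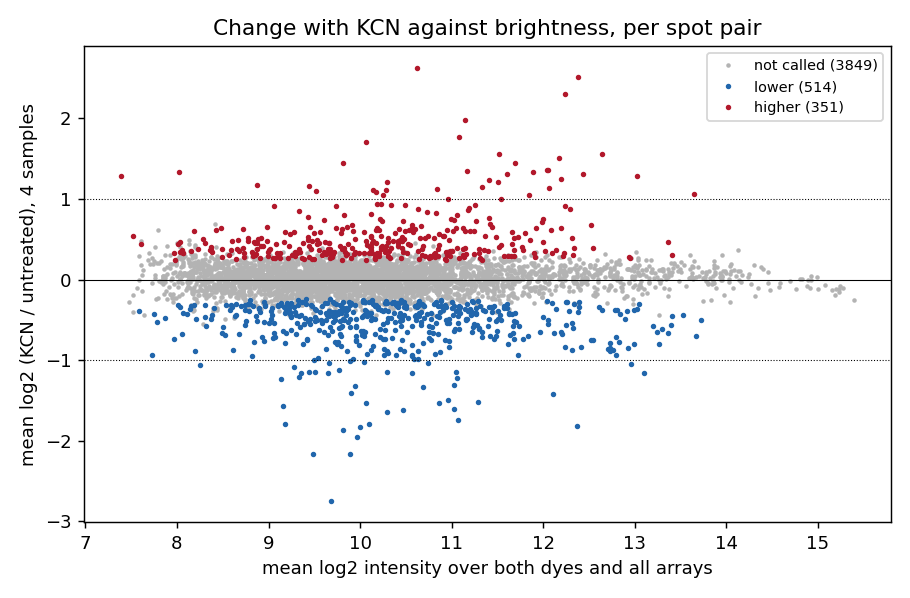
Mean log2 ratio of KCN over untreated in 4 samples (vertical) against mean log2 intensity over both dyes (horizontal), 1 point per spot pair, red for 351 higher, blue for 514 lower and grey for pairs that did not pass; dotted lines mark 2-fold. Of the rises of at least 2-fold, 22 of 37 lie in the brightest of 5 bins, while the largest rise lies at a mean log2 intensity of 10.62.

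KCN was in Cy3 in sample 3 alone, so a dye effect does not cancel in the mean of 4. With a dye term in the model, 382 pairs were higher and 474 lower, among them 275 of the 351 and 399 of the 514 called without it. That model averaged sample 3 with the mean of samples 1, 2 and 4, so sample 3 weighed as much as those together. Its spread came from samples 1, 2 and 4 alone. In the 3 samples with KCN in Cy5, 1032 pairs passed when fitted without sample 3 and with values required in all 3, and 1024 of these were measured in it. The fit without sample 3 that required at least 2 values called 465 higher and 555 lower. In sample 3, 818 of the 1024, or 79.9%, had the same direction, against 61.5% over all pairs tested, called or not. Over the called pairs the values of sample 3 and of the other samples correlated, with r = 0.812 across pairs, which are not independent replicates, and a slope of 0.825 on the other samples' mean. Without that choice of pairs, sample 3 correlated at 0.632 with the other samples' mean. Picking pairs by large changes in the other samples can itself raise r. Over all pairs, samples 1, 2 and 4 correlated at 0.815, 0.726 and 0.776 with each other. Sample 3 correlated at 0.519, 0.629 and 0.592 with samples 1, 2 and 4. As Cy5 over Cy3, arrays of opposite orientation correlated between -0.640 and -0.412, and arrays of the same orientation from different samples between 0.593 and 0.803.

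**Figure D3:**
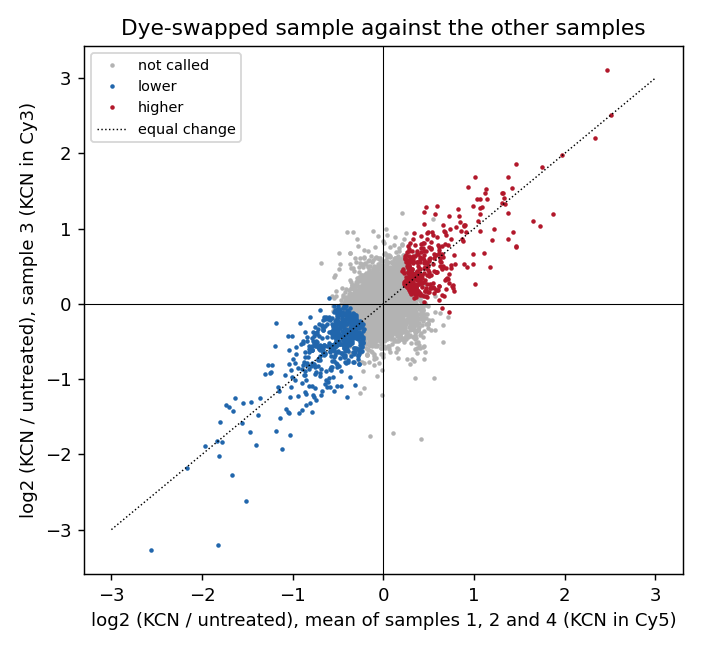
Log2 ratio of KCN over untreated in sample 3, with KCN in Cy3 (vertical), against the mean of samples 1, 2 and 4, with KCN in Cy5 (horizontal), 1 point per spot pair, coloured by call, with the line of equal change dotted. Larger changes lie along the line, and 79.9% of the pairs that passed without sample 3 had the same direction in it, against 61.5% of all pairs tested.

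A dye effect of its own passed the test in 1 of 4675 pairs (limma, Benjamini-Hochberg adjusted p = 0.023; spots 2351 and 2352, spots_2351_2352, at 1.11 on the log2 scale). This pair, named after its values were seen, had a KCN log2 ratio of -0.70 beside the dye term (adjusted p = 0.003) and of -0.14 without it (adjusted p = 0.81). At an unadjusted p under 0.05, 869 pairs passed for a dye effect. This was 18.6% of the 4675. With no dye effect a share of about 0.05 would pass only if sample 3 varied no more than the other samples. The spread came from those other samples alone. With array weights, which gave sample 3 the lowest weight, 0.35, 161 pairs passed at an unadjusted p under 0.05. The excess over 0.05 therefore does not by itself show a dye effect. Over the alternatives that tested it, the number of pairs with a dye effect after adjustment ran from 0 to 187. As 1 biological sample was swapped, the dye effect and what was particular to sample 3 cannot be told apart.

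The counts moved by over 1.5 times with some choices. With array weights 765 were higher and 838 lower, with the deposited log ratios 232 and 333. Without sample 2 there were 174 higher and 306 lower, without sample 4 184 and 302, and with quantification day 2 alone (samples 3 and 4) 182 and 314. The day 2 fit, on 2 samples, gave the 4 named pairs the same standard error of 0.18, so its counts act as a threshold on size.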

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

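The fit over unlisted spots was chosen after the data were seen; the counts of sign patterns were planned. Of 22 groups of 4 samples or 8 arrays tested for a value far from the rest, 4 passed. The chance rate of about 1 in 20 holds for normal values and separate groups. These groups overlap, as flags set by hand are part of all flags, and counts need not be normal. Array 2 of sample 3 had 3129 flagged spots, against a median of 1150 over the 8 arrays, and 1283 spots flagged by hand, against a median of 19. Array 1 of sample 2 had a median Cy5 intensity of 3003 and 71 saturated Cy5 spots, the highest of the 8 arrays in each. These are counted over listed spots for saturation and over all spots for flags.

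A signal also appeared in spots that the authors' value table does not list. In a fit over all spots, 55 of 1662 unlisted pairs passed with limma at an adjusted p under 0.05, which was 3.31%, against 15.4% of the listed pairs in the same fit. Of these, 38 were higher and 17 lower, from 1.96 to -1.34 on the log2 scale. Of the unlisted pairs, 1023 were above background on all 8 arrays in both dyes. What these spots hold is not given in the sources used here.

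The 865 called pairs were set beside counts from the other sign patterns of the 4 samples. Among the 8 patterns that differ by more than a turn of all signs, 1 gave as many calls, the real one, and the highest of the others was 0 with limma. At an unadjusted p under 0.05 the real pattern had 1514 pairs and turning sample 3 alone, the dye direction, gave 476. The 8 splits are too few for a share under 0.05.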

How the results depend on the processing

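Alternatives for all spots, odd or even spots, background mean, the array with most flagged spots left out and a day term were added after the data were seen. Lower exceeded higher in all 29 alternatives, the share of calls that were higher ran from 36.3% to 47.7%, and at most 1 called pair changed sign in any. All had ratios centred near 0 within each array, and their median log2 ratios lay between 0.001 and 0.018. The balance of rises and falls rests on that centring, which no alternative removed. The 4 named pairs kept direction and call in all 116 values. Named pairs by rule, and most called pairs, agreed in all 4 samples, so dropping or reweighting samples could not turn them. In 4 values the fold moved by over 1.5 times. Deposited log ratios gave 3.38 for spots_7829_7830 and -3.67 for spots_1015_1016. On day 1 spots_4455_4456 stood at -1.48 and on day 2 at -2.86. Of the counts of higher and lower pairs, 48 stayed within 1.5 times and 10 did not. Array weights gave 765 higher and 838 lower, with weights of 1.70, 2.95, 0.35 and 0.57 for samples 1 to 4. Deposited log ratios gave 232 and 333, and day 2 alone 182 and 314, the last with the same standard error of 0.18 for the 4 named pairs. A dye term, with sample 3 weighing as much as the others together, gave 382 and 474, of which 275 and 399 were main calls. Leaving out 1 sample gave 174 to 465 higher and 302 to 555 lower. Sample 2 left out gave 174 and 306, and sample 4 184 and 302. The cause was not tested. Aquantile, 1 of the 29, changes only brightness after loess and could move no value. The dye effect rested on 1 swapped sample, and its count of 1 moved, the cause not tested: normexp offset 0 gave 2, median centring 6, deposited values 9, duplicateCorrelation 187 and a day term 60, and leaving out 1 sample 1 to 112, the 112 without sample 4. The dim filter, flagged spots kept, signal median, technical array 2, eBayes with trend and robust, array weights, even spots and background mean each gave 0 (limma, 161 to 891 at an unadjusted p under 0.05). No dye effect could be estimated without sample 3 or on day 1, and on day 2 none could be tested, with 0 residual degrees of freedom. Gene lists, camera and fry were not run, since spots have no gene names. A pair near background has a ratio limited by signal over background: 5 of 8 arrays with KCN were above it for the largest fall.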

Other observations

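Tests of the spot numbers and of the dye-swapped sample were chosen after the results were seen; the brightness tests were chosen before their own results were seen, except for the shares of rises and falls within single samples. Spot pairs 16 numbers apart changed alike. The mean changes correlated at 0.312 at distance 16, 0.270 at 32, 0.113 at 48 and 0.118 at 64, against -0.055 to 0.059 at the 70 even distances up to 160 that are not multiples of 16. Of the higher pairs, 30.8% had a neighbour at distance 16 called the same way, and of the lower pairs 47.9%, against 23.4% and 28.0% as the highest of 1000 shuffles of the calls. A position or dye bias shared by the slides would turn sign in sample 3, whose ratios correlated with neighbours in the other samples at 0.229. Carry-over by a print pin would leave out the 0.312 at distance 16, where spots lie in different blocks, only if each block had its own pin. That was not established here, so carry-over stays open. Probes numbered along the chromosome, with operon genes changing together, may account for it, but the correlation did not fall evenly to 0.118 at distance 64, and no gene names allow a direct test. Neighbouring wells of the source plates were not tested.

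Sample 3 correlated less with the others than they did among themselves. After correction for the technical correlation its highest value was 0.722, against 0.828 to 0.945 among samples 1, 2 and 4. For noise that differs between its arrays to bring it down from the lowest of those, its technical correlation would have to be 0.493, but it was 0.767, within the 0.742 to 0.824 of the 4 samples, which argues against such noise as the whole cause. Noise shared by both of its arrays stays open. Dye bias of single probes stays open too, because 1 swapped sample cannot tell it from what was particular to sample 3, a biological difference included.

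Rises of at least 2-fold sat mostly in the brightest of the 5 bins of pairs. Because brightness averaged the KCN and untreated signals, rises were moved toward brighter bins and falls toward dimmer ones. This held in every sample and under every correction, and none of the tests below removed it. Shrinking of dim ratios by the offset and background correction was tested with offset 0 and with subtraction. In these, 53.8% and 57.9% of such rises were in the brightest bin, against 9.6% and 10% of falls (Fisher's exact test, two-sided, p = 4.82e-06 and 1.66e-06). In the main fit the shares were 59.5% and 11.9%. They moved little, which argues against shrinking as the whole cause. With no correction, where background left in the signal can itself shrink dim ratios, they were 59.5% and 12.8% (Fisher's exact test, two-sided, p = 3.03e-05). For a bend of the dye ratio left by loess, the brightest bin of sample 3 alone held 21 rises of at least 2-fold and 15 falls (exact binomial p = 0.405, two-sided). The samples with KCN in Cy5 differed among themselves. Their brightest bins held 22 and 4 in sample 1 (exact binomial p = 0.000534) and 24 and 10 in sample 2 (exact binomial p = 0.0243). That of sample 4 held 22 and 19 (exact binomial p = 0.755). As shares, the brightest bin of sample 3 held 46.7% of its 45 rises and 22.1% of its 68 falls (Fisher's exact test, two-sided, p = 0.00761), the direction seen in samples 1, 2 and 4, but 1 swapped sample leaves the bend open. No biological explanation was tested.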
